A study of Mus musculus with 14 samples.

How the data were processed

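The series holds 14 samples of mouse neural stem cells, which per the labels were isolated from the subventricular zone of adult animals. Single-cell 3′ libraries (10x Genomics, oligo(dT) capture) were made from cells cultured with BMP4 for 3 days, from cells cultured with EGF, and from freshly isolated cells of wildtype and Aplp1 knockout mice. A pair of hash tag libraries counts 3 antibody-linked oligonucleotide tags that mark the cells of individual mice within each fresh library, and the antibodies bind MHC class I and CD45. The other 8 samples are RNA immunoprecipitations (RIP) from cultured neurospheres, with 2 replicates each of wildtype input, wildtype IgG precipitate, wildtype CPEB4 precipitate and CPEB4 precipitate from cells labelled knockout. Groups and replicate numbers were taken from the sample labels, and table columns were matched to samples by genotype, fraction and replicate number.

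All values used are whole-number counts deposited by the authors, per gene and cell, per tag and barcode, or per gene and RIP library. Per the submitters' processing notes, the genome build was mm10 and the tools were Bowtie2, SAMtools and Cell Ranger. Their versions, the step each served, the annotation, the strand setting and the filters on cells are not given in the sources used here. The culture counts cover 27998 genes each, the fresh counts cover 13288 and 13338 genes, of which 12470 are shared, and the RIP counts cover 27144 genes. No line of these tables lacks a gene identifier, so none was left out of library sizes. Ensembl identifiers were paired with symbols through a gene name table, which named 98.2% of the RIP identifiers, 98.7% of the culture identifiers and 99.0% of the fresh identifiers. Gene positions, biotypes and lengths (the span from start to end) came from RefSeq annotation of GRCm38.p6, the assembly of the mm10 build. Whether the fresh counts are reads or molecules is not given in the sources used here.

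The tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined. In each tested comparison the deleted gene was named, then the 10 genes with the largest log2 fold change each way among those past the threshold, with a mean of 10 or more raw counts in the higher group and no overlap between replicates, then the 2 members of smallest p of each list with 3 or more members past it. In the cultures these were the 10 largest ratios each way among genes with 500 or more counts over both libraries, and the 2 largest changes each way in each list. Predicted genes, ribosomal pseudogenes and identifiers without a symbol were passed over. Some genes that this rule selects are not used here. The 22 lists cover BMP response, EGF and ERK response, S phase, G2/M phase, quiescence and astrocyte, neurogenic progenitor, neuroblast, APP family and processing, interferon response, CPEB and poly(A) tail regulation, cleavage and polyadenylation, autism risk, ER stress and unfolded protein response, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded, cholesterol synthesis, immediate early and dissociation stress, glycolysis, oligodendrocyte, microglia/macrophage, and endothelial genes.

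Each culture condition is 1 library, so no test was made between the cultures. Counts were summed over cells and given as CPM of the library with exact Poisson or binomial 95% intervals. Ratios were taken for genes with 10 or more counts over both libraries, with a pseudocount of 0.5 counts in the list medians, and each list median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. For genes at 0 in a library, the fold is a bound against 3 counts of that library. Shares of cells with a transcript were taken after thinning every cell to 4500 counts, which left out no cell, and carry exact Clopper-Pearson intervals. Intervals and floors cover counting error only. Neither doublets nor free RNA were removed, and the cultures were not divided into cell types.

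In the fresh libraries a cell was given to a mouse when it had 10 or more tag counts and 75% or more of them were of the same tag. Tag tables and cells were joined by barcode and genotype. The planned filter of 500 genes per cell left 135 wildtype and 217 knockout-labelled cells, of which 16 and 17 had a mouse, so all deposited cells were used instead, a choice made after the data were examined. Mitochondrial genes are not among the genes of these tables, so the planned mitochondrial filter was not used. Among the 7741 genes detected in 20 or more cells, 213 gene pairs had counts correlated above 0.8 across cells. Of the 198 pairs with both positions, 89.4% lay within 10 kb of each other, against 0.009% of random pairs. The lower member of each pair was left out of clustering, since such pairs can hold the same reads. Clustering used scanpy 1.11.5 with counts scaled to 10000 per cell, a log, 2000 variable genes without Aplp1, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9). Clusters were called after the fixed markers, and clusters with fewer than 3 markers raised by 1.5-fold, or with markers of another class ahead of their own, stayed unnamed. No doublet caller was run. Cells with mixed tags were left out of the mouse sums.

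Counts were summed per mouse and tested with edgeR 4.0.16 (filterByExpr, TMM, robust estimateDisp and glmQLFit, glmQLFTest) at a Benjamini-Hochberg false discovery rate of 5%, in R 4.3.3. The same test was run on the 8 RIP libraries in a common fit of 4 groups without a replicate term. Standard errors (SE) of log2 fold changes were derived from the edgeR test, as the absolute log2 fold change divided by the square root of its F statistic. Lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation. Shares of classes were compared by exact two-sided permutation over mice. Other numerical work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives were DESeq2 1.42.0 (its size factors and its Wald test), scaling by total counts, no filter and a stricter filter (50 or more counts in 2 libraries), the replicate number as a block, fits on the 4 libraries of a contrast, a fold of 2 or more, a tag share of 90%, HTODemux of Seurat 5.3.0 at its quantile of 0.99, other Leiden resolutions, and leaving out each library or mouse in turn. Added after the data were examined were the contrasts of IgG and knockout-labelled precipitates with input, removal of background loci (genes with 1% or more of the counts of both IgG libraries), tag minimums of 3 and 20 counts, and the fits with and without genes of correlated pairs.

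The steps were tested on simulated data drawn from the real means and library sizes (with the fitted dispersions where replicates exist), with 100 genes changed 2-fold and 100 changed 4-fold. In the comparison of wildtype with knockout-labelled CPEB4 precipitates, over 16230 genes, 0 of the 2-fold and 2 of the 4-fold changes were called, with 1 false call among 3. Sums per mouse, over 1008 genes, recovered 44 of the 2-fold and 93 of the 4-fold changes, with 6 false calls among 143. For the cultures, over 14517 genes, the exact 95% interval held the true ratio of 94 of the 2-fold and 97 of the 4-fold genes. Positions of reads within 3′UTRs and CPEB binding motifs were not analysed here, because no genome sequence was used.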

Results

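Neural stem cells of the adult mouse subventricular zone, a niche that makes neurons throughout life, were profiled in 14 samples. The series was designed to compare active with quiescent cells and Aplp1 knockout with wildtype cells, and to measure which mRNAs CPEB4 binds. CPEB4 is a cytoplasmic polyadenylation element binding protein that regulates poly(A) tails and translation. The BMP4 culture library held 887 cells and 17313999 counts (median 17355 counts and 4166 genes per cell), and the EGF culture library 1410 cells and 33603623 counts (median 22866.5 counts and 4523 genes). Freshly isolated cells numbered 2209 in the wildtype library, with 1133263 counts and a median of 364 per cell, and 1879 in the library labelled Aplp1 knockout, with 1227695 counts and a median of 424. The 8 RIP libraries held between 10054346 and 17466296 counts each.

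The first comparison set cells cultured with BMP4 for 3 days, a signal that brings cultured neural stem cells into quiescence, against cells cultured with the mitogen EGF. All 14 measured genes of the BMP response list were 2-fold or more higher in the BMP4 library, with a median log2 ratio of 5.75. Among them Smad6, an inhibitor of BMP signalling, had 800 counts against 3, a ratio of 518 (176 to 2515), and Gfap, the intermediate filament of astrocytes, had 732 against 2, a ratio of 710.4 (196 to 5877). Of the 17 quiescence and astrocyte genes, 15 were 2-fold or more higher in the BMP4 library and 0 in the EGF library (median 2.10). The water channel Aqp4 led this list at 794 CPM against 0.417 CPM, a ratio of 1906 (1136 to 3488), followed by Fxyd1, a regulator of the sodium pump, at 286 (78.6 to 2375). Medians of both lists lay above those of all 10000 random lists matched on expression (percentile 100).

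Among genes with 500 or more counts over both libraries, several were almost confined to the BMP4 library. Inpp5j, an inositol phosphatase gene, had 1552 counts against 0, at least 1004-fold higher, and Gja3, a gap junction gene, had 771 against 0, at least 499-fold higher. Cidea, which encodes a lipid droplet protein, had 6214 counts against 2, a ratio of 6030.2 (1669 to 49804), and the neuropeptide gene Npy had 738 against 2, a ratio of 716 (198 to 5925). Ratios of Stum (2185, 391 to 86394), Fam107a (1477, 264 to 58413) and the proteoglycan gene Bgn (1213, 217 to 47988) rested on 1 count each in the EGF library. Caln1 stood at 162 CPM against 0.238 CPM, a ratio of 679 (344 to 1573). In the other direction, the lactate transporter gene Slc16a3 had 980 counts in the EGF library and 1 in the BMP4 library, 505-fold more (90.4 to 19964). Nptx2, a secreted pentraxin, was 147-fold higher with EGF (62.9 to 454), Golga7b 142-fold (48.3 to 688), Trp53i11 138-fold (107 to 183), Scml4 136-fold (37.5 to 1128) and the homeobox gene Barx2 116-fold (45.3 to 428). Adm, which encodes a vasodilator peptide, was 64.1-fold higher with EGF (40.5 to 108), Car3, a carbonic anhydrase, 50.2-fold (25.4 to 117), Nrgn 49.7-fold (35.1 to 72.8) and the surface protein gene Cd24a 45.4-fold (37.9 to 54.8).

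Cell cycle genes were lower in the BMP4 library without exception. All 24 G2/M phase genes and all 24 S phase genes were 2-fold or more higher with EGF, with median log2 ratios of -3.27 and -2.46, below those of all random lists (percentile 0). The mitotic checkpoint kinase gene Bub1 was 17.9-fold higher with EGF (11.1 to 31.0) and the kinesin gene Cenpe 15.5-fold (12.1 to 20.2). Uhrf1, which maintains DNA methylation at replication, was 13.2-fold higher (10.7 to 16.5) and the histone chaperone gene Chaf1b 9.42-fold (6.73 to 13.6). After thinning every cell to 4500 counts, 7.10% of BMP4 cells (63 of 887, 95% interval 5.50 to 9.00) and 51.8% of EGF cells (730 of 1410, 49.1 to 54.4) carried a transcript of Mki67, Top2a or Cdk1. Without thinning these shares were 19.1% and 78.9%. The BMP target Id1 was found in 75.5% of thinned BMP4 cells and 6.74% of thinned EGF cells, and Egfr, the EGF receptor gene, in 6.09% and 28.4%. Dcx, a neuroblast gene, was found in 0.113% and 0.355%, and Olig2 in 41.0% and 76.4%. Gfap was found in 13.9% of thinned BMP4 cells and 0 of 1410 thinned EGF cells (upper limit 0.261%). No cell type of these cultures that should lack a gene was at hand to measure free RNA.

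Stage markers of neurogenesis moved in both directions. Of 15 neurogenic progenitor genes, 5 were 2-fold or more higher with BMP4 and 6 with EGF (median -0.24, percentile 17.4). Hes5, a Notch target, was 10.4-fold higher with BMP4 (9.66 to 11.3) and Dlx2 4.80-fold (3.63 to 6.40), while the intermediate filament gene Nes was 21.1-fold higher with EGF (17.9 to 25.0) and Egfr 4.63-fold (4.10 to 5.24). The 8 neuroblast genes had a median of -0.63 (percentile 5.63), with Nrxn3 15.7-fold higher with BMP4 (13.1 to 19.1) and Sox11 4.44-fold higher with EGF (4.21 to 4.69). Oligodendrocyte genes were higher in the BMP4 library for 5 of 8 members (median 3.17, percentile 100). The myelin gene Mbp had 418 counts against 8, a ratio of 101 (51.0 to 236). Endothelial (6 genes, median 0.80, percentile 79.8) and microglia/macrophage genes (4 genes, median -0.20, percentile 30.3) were within the middle 95% of random lists. The EGF and ERK response list had a median of 0.22 (percentile 74.4), with Ccnd1, the cyclin of G1 entry, 37.7-fold higher with EGF (34.3 to 41.4), Phlda1 4.29-fold higher with EGF (3.82 to 4.85), and the ERK inhibitor gene Spry1 2.71-fold higher with BMP4 (2.57 to 2.86).

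Genes of growth and metabolism made up other groups. Ribosomal proteins had a median of -0.82 (34 genes, percentile 0.03), with 10 members 2-fold or more higher with EGF. Cholesterol synthesis genes had a median of -0.91 (19 genes, percentile 0), and 8 of them, led by Fdps at 3.65-fold (3.35 to 3.97) and Sqle at 2.86-fold (2.66 to 3.06), were 2-fold or more higher with EGF. Glycolysis genes had a median of -0.21 (16 genes, percentile 24.2). Its phosphofructokinase gene Pfkm was 7.08-fold higher with BMP4 (6.39 to 7.86) and its hexokinase gene Hk2 5.01-fold higher with EGF (4.18 to 6.05). Oxidative phosphorylation genes (25 genes, 0.35, percentile 97.2) and the 13 mitochondrially encoded genes (0.64, percentile 99.1) had positive medians, and the median mitochondrial share per cell was 9.15% with BMP4 and 6.12% with EGF. Of 20 immediate early and dissociation stress genes, 13 were 2-fold or more higher with BMP4 (median 1.45, percentile 100), led by Fosb at 17.2-fold (14.7 to 20.2) and the cytokine signalling inhibitor Socs3 at 15.8-fold (11.4 to 22.4). The ER stress and unfolded protein response list (20 genes) had a median of 0.69 (percentile 98.6). Its chaperone genes Dnajb9 and Hspa5 were 4.43-fold (4.00 to 4.91) and 2.19-fold (2.10 to 2.28) higher with BMP4, and Trib3, with 0 counts against 81, was at least 13.9-fold lower. Interferon response genes had a median of 0.59 (17 genes, percentile 83.9).

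Genes of the proteins and RNA processing steps named in the series also differed between the cultures. App, the amyloid precursor gene, stood at 400.6 CPM with BMP4 and 57.6 CPM with EGF, a ratio of 6.95 (6.61 to 7.32), and the presenilin gene Psen2 had a ratio of 5.21 (4.13 to 6.61). The APP family and processing list had a median of 0.86 (17 genes, percentile 99.4). Among 30 genes of CPEB and poly(A) tail regulation (median -0.05, percentile 22.3), the binding protein genes Cpeb3 and Cpeb2 were 7.01-fold (5.63 to 8.78) and 4.31-fold (3.74 to 4.98) higher with BMP4. The poly(A) polymerase gene Tent2 was 2.84-fold higher with EGF (2.35 to 3.46) and the poly(A) binding protein gene Pabpc1 2.40-fold (2.33 to 2.47). The cleavage and polyadenylation list had a median of -0.41 (23 genes, percentile 1.41), with Nudt21, a regulator of poly(A) site choice, 3.81-fold higher with EGF (3.57 to 4.07) and the neuronal RNA-binding gene Elavl4 5.20-fold (3.85 to 7.17). Autism risk genes had a median of 0.50 (53 genes, percentile 98.9), with the secreted glycoprotein gene Reln 10.3-fold higher with BMP4 (6.00 to 18.9). Over all 14502 genes with 10 or more counts, 3349 were 2-fold or more higher with BMP4 and 2235 with EGF, and the median log2 ratio was 0.15. TMM factors lowered every log2 ratio by 0.141. With 1 library per condition these ratios have no replicate check, and they compare the libraries, not the conditions.

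**Figure D1:**
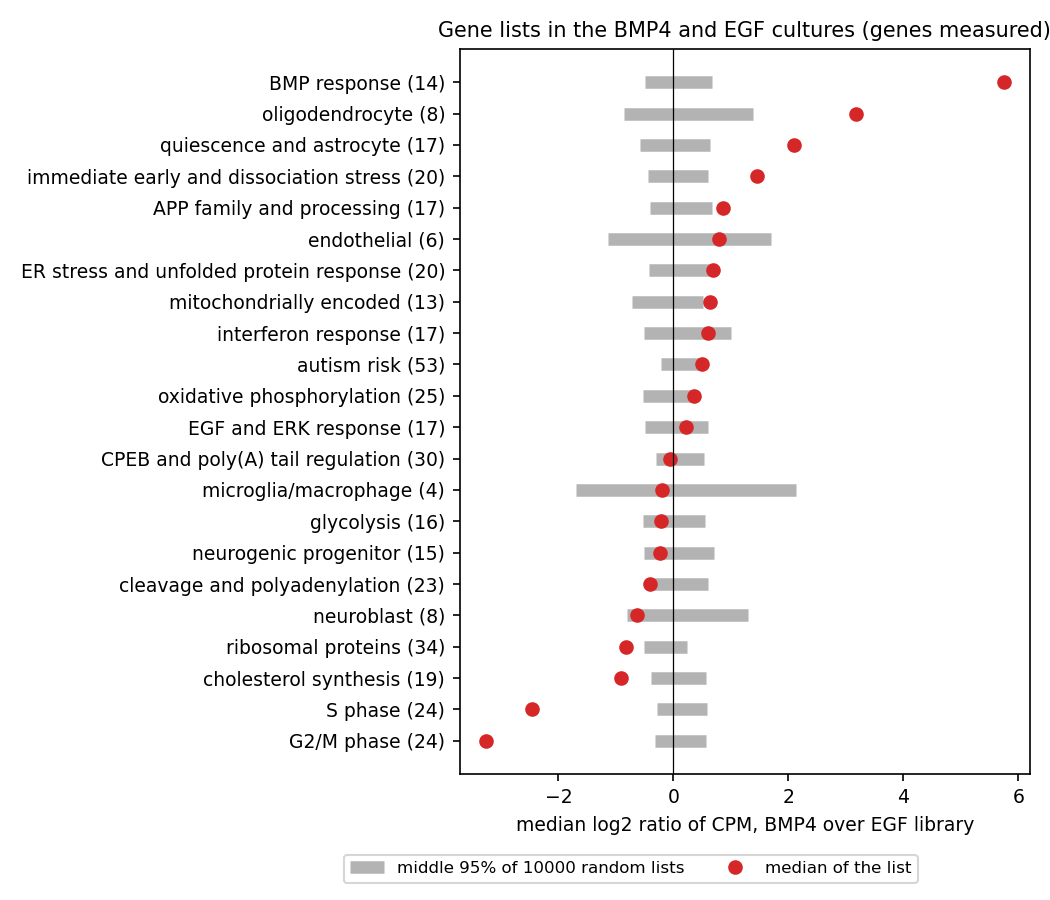
Median log2 ratio of CPM (BMP4 over EGF library) of each gene list, with the number of genes measured in brackets; grey bars hold the middle 95% of 10000 random lists matched on expression. The BMP response list lies highest at 5.75 and the G2/M phase list lowest at -3.27.

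The second comparison was between freshly isolated cells of mice labelled Aplp1 knockout and of wildtype mice. Each genotype is 1 library, so genotype and library cannot be told apart. The p-values over mice in this comparison do not measure differences between libraries. Aplp1, a relative of the amyloid precursor gene (ENSMUSG00000006651, chromosome 7, 30434980 to 30445582 in GRCm38.p6), had 246 counts in the wildtype library (217 CPM) and 54 in the library labelled knockout (44.0 CPM), 4.94-fold fewer (3.66 to 6.75). Part of this fold can lie in cell makeup. Cells of the class called quiescent NSC/astrocyte-like below made up 55.5% of the wildtype library and 39.3% of that labelled knockout. Within this class Aplp1 stood at 385 and 122 CPM, a smaller difference. Among cells assigned to a mouse, the 3 wildtype mice held 4, 15 and 22 Aplp1 counts (101, 229 and 218 CPM). The mice labelled knockout held 0, 7 and 0, with upper limits of 57.6 CPM for tag 1 and 53.6 CPM for tag 3, and 94.2 CPM (37.9 to 194) for tag 2. With a tag minimum of 3 counts, tag 2 carried 22 of the 24 Aplp1 counts of the tagged cells labelled knockout, 91.7%, although it carried 39.5% of all their counts. Its level of 124 CPM (77.5 to 187) compared with 230.2 to 255 CPM in the wildtype mice, so the mouse with tag 2 is called knockout only by its label. Aplp1 counts were 0 in the microglia/macrophage-like cells of both libraries, which hold 39064 counts, too few to measure free Aplp1 RNA. Of its relatives, Aplp2 was 1.42-fold lower in the library labelled knockout (1.17 to 1.73) and App had a ratio of 1.02 (0.753 to 1.39). Both carry counting error only and take no account of cell makeup.

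**Figure D2:**
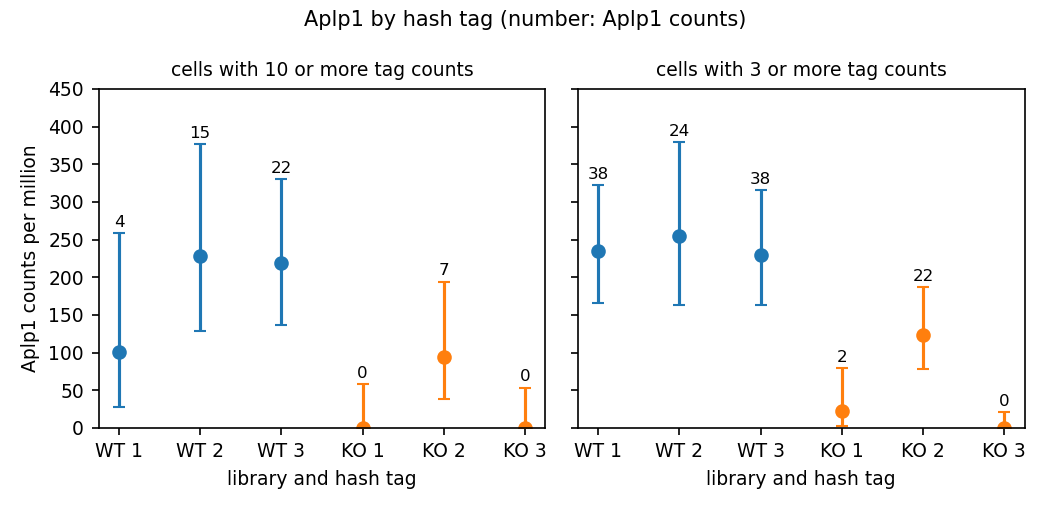
Aplp1 CPM by hash tag in the wildtype (WT) library and the library labelled knockout (KO), in cells with 10 or more and with 3 or more tag counts; bars are exact 95% Poisson intervals and numbers are Aplp1 counts. With 3 or more tag counts, tag 2 of the library labelled knockout holds 22 counts and tags 1 and 3 hold 2 and 0.

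Clusters were called quiescent NSC/astrocyte-like (1964 cells), active NSC/transit amplifying-like (947), neuroblast-like (516), microglia/macrophage-like (72), mature neuron-like (63) and endothelial-like (39), and 487 cells stayed unnamed. Per mouse, quiescent NSC/astrocyte-like cells made up 65.7% ± 8.09 of assigned wildtype cells (SD, n = 3) and 57.3% ± 5.59 of cells labelled knockout (n = 3). Active NSC/transit amplifying-like cells made up 8.19% ± 2.08 and 11.0% ± 3.71, neuroblast-like cells 1.61% ± 0.869 and 1.89% ± 1.88, and microglia/macrophage-like cells 7.48% ± 3.72 and 10.1% ± 1.09. Endothelial-like cells stood at 3.95% ± 1.86 and 5.58% ± 3.26, and mature neuron-like cells at 0.407% ± 0.704 and 1.00% ± 0.450. None of the differences passed an exact two-sided permutation test over 3 against 3 mice, which cannot go below p = 0.1 (smallest p = 0.3, adjusted p = 0.525). The share of cells with a mouse ranged from 98.6% of microglia/macrophage-like cells to 2.91% of neuroblast-like cells, so these makeups are those of tagged cells. Over whole libraries, quiescent NSC/astrocyte-like cells made up 55.5% of wildtype cells and 39.3% of cells labelled knockout, and active NSC/transit amplifying-like cells 19.7% and 27.2%.

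**Figure D3:**
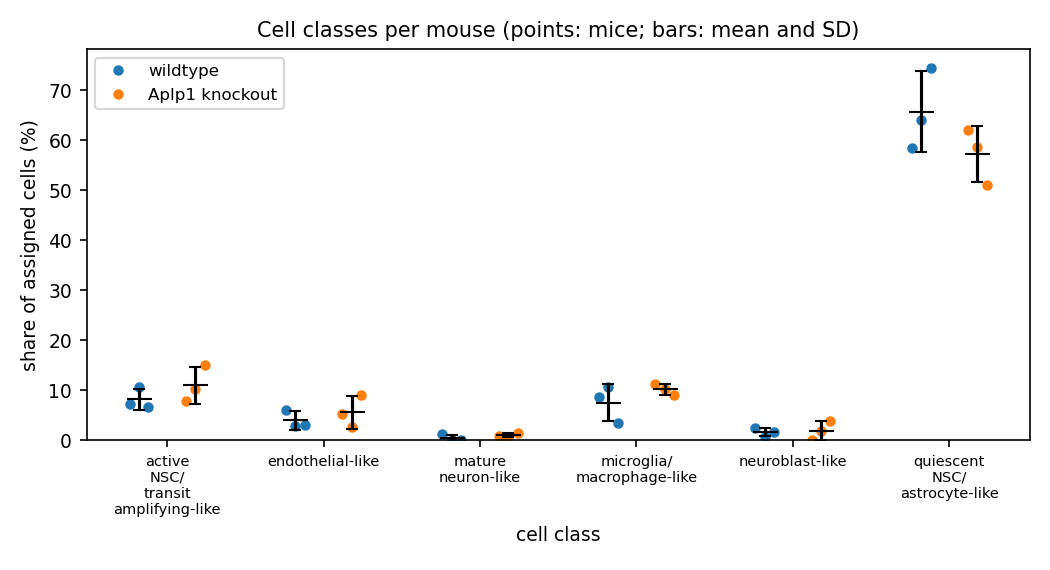
Share of assigned cells in each named class, in percent, for 3 wildtype mice and 3 mice labelled Aplp1 knockout; points are mice, horizontal marks means and bars SD. Quiescent NSC/astrocyte-like cells average 65.7% and 57.3%.

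In sums over all assigned cells, 1 of 1109 tested genes was higher in the mice labelled knockout and 0 were lower. Ccl4, a chemokine gene of activated microglia (ENSMUSG00000018930, chromosome 11, 83648624 to 83664683), rose by 2.21 on the log2 scale (SE 0.43, edgeR adjusted p = 0.0346), from 328 ± 131 to 1452 ± 702 CPM (SD, n = 3), and was higher in 3 of 3 mice labelled knockout than in any wildtype mouse. Of its 246 counts in assigned cells, 245 lay in the microglia/macrophage-like class, of which Ccl4 is a defining gene. Within that class it stood at 3380 ± 1317 CPM in wildtype mice and 8798 ± 1389 CPM in mice labelled knockout (n = 3 each, exact permutation p = 0.1, the smallest this design allows). These values rest on 7 to 16 cells of the class per mouse and on 12 to 18 Ccl4 counts per wildtype mouse. In knockout tag 1 a single cell held 35 of the 96 counts. The Ccl4 call was lost, leaving 0 genes, with DESeq2 (133 genes at an unadjusted p under 0.05), with a tag share of 90%, with HTODemux, with 20 or more tag counts, with the tag number as a block, and without wildtype tag 1, wildtype tag 3, knockout tag 1 or knockout tag 3. Genes at an unadjusted p under 0.05 numbered 59, or 5.32% of those tested. Aplp1 itself did not pass the filter on low counts, and without that filter its log2 fold change was -2.43 (edgeR adjusted p = 0.805). Without knockout tag 2 it passed the filter with 0 counts in both remaining mice labelled knockout, and the fitted log2 fold change moved to -6.68, set by these 0 counts (edgeR adjusted p = 0.285).

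The immediate early and dissociation stress list, which holds genes that cells switch on within minutes of a stimulus, was higher in mice labelled knockout (11 tested genes, median log2 fold change 0.62, camera adjusted p = 4.05e-05). That call was lost at adjusted p = 0.15 with an estimated correlation. All 11 genes had positive log2 fold changes, 0 passed over all genes, and 2 passed when adjusted over the list alone, both named after their values were seen. These were Fos (0.98, SE 0.29, edgeR adjusted p = 0.0176 over the list) and Klf4 (1.61, SE 0.49, edgeR adjusted p = 0.0176 over the list). A cluster of 161 cells led by Klf4, Nr4a1 and Fos, which stayed unnamed, held 55 wildtype cells and 106 cells labelled knockout. Genotype cannot be told from library for this list or this cluster. No other of the 17 lists with 2 or more tested genes passed (smallest camera adjusted p = 0.301). Within the quiescent NSC/astrocyte-like class edgeR called 0 of 533 genes, with 26 at an unadjusted p under 0.05 and 0 called by DESeq2. Without knockout tag 2 it called Nav2 as higher, without knockout tag 3 Nav2 as higher and Pdpn as lower, and with the tag number as a block Nav2 and Klf13 as higher. Over all assigned cells, Ccl4 passed also without the mouse of tag 2, whose knockout label is in doubt (2.43, edgeR adjusted p = 0.00607).

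The third comparison addressed which RNAs are bound by CPEB4 in neurospheres, by RIP with a CPEB4 antibody, an IgG control, the input RNA and precipitates labelled Cpeb4 knockout. Cpeb4 itself (ENSMUSG00000020300, chromosome 11, 31870104 to 31935635) had 808 and 628 counts in the inputs, 239 and 755 in IgG, 3109 and 1025 in the wildtype CPEB4 precipitates, and 4825 and 1285 in those labelled knockout. At 153 ± 102 CPM in wildtype and 241 ± 13.6 CPM in knockout-labelled precipitates (SD, n = 2), its log2 fold change was -0.65 (SE 0.56, edgeR adjusted p = 1). Counts over a whole gene can lie outside a deleted part, so this does not test the label, and these libraries are called knockout only by their labels. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries.

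A few loci filled the precipitates. Cmss1, Filip1l, Zc3h7a, Arhgap21 and the ribosomal RNA-related Gm42418 were among 17 genes with 1% or more of the counts in both IgG libraries. Together these held 75.4% and 70.8% of IgG counts, 48.4% and 55.9% in the wildtype CPEB4 precipitates, 35.9% and 75.2% in those labelled knockout, and 0.232% and 0.334% in the inputs. Mitochondrial genes had 0 counts in both inputs over all 37 genes, against 29672 and 9841 in IgG, 11627 and 166877 in the wildtype CPEB4 precipitates and 18314 and 10566 in those labelled knockout.

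**Figure D4:**
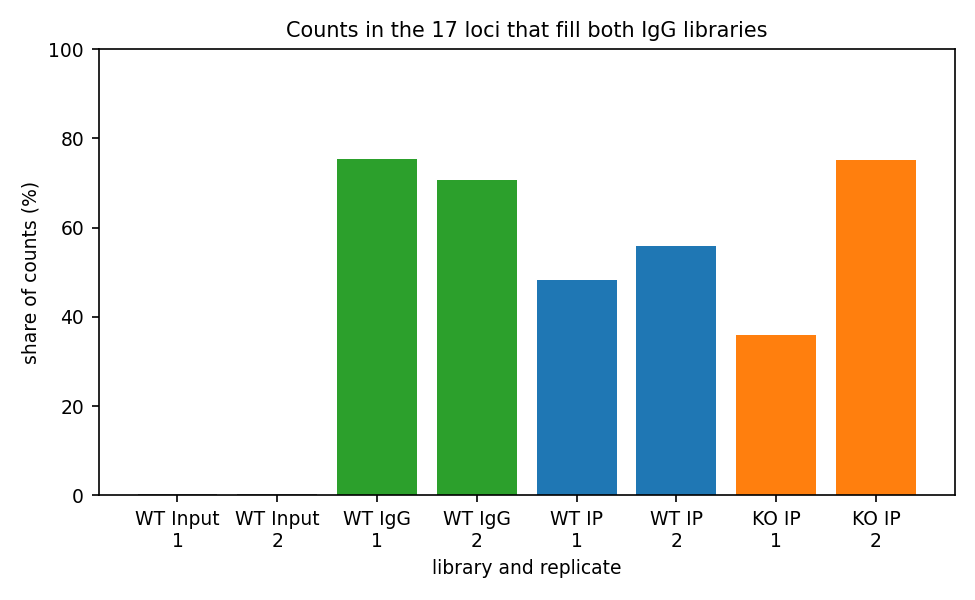
Share of counts, in percent, in the 17 genes that each hold 1% or more of both IgG libraries; each bar is 1 library, 2 replicates per group, with KO the label. Inputs stand at 0.232% and 0.334%, and the precipitates labelled knockout at 35.9% and 75.2%.

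Between wildtype and knockout-labelled CPEB4 precipitates, edgeR called 0 of 17062 genes higher and 0 lower, with 131 (0.768%) at an unadjusted p under 0.05 and 0 called by DESeq2. Cholesterol synthesis genes had a median log2 fold change of -0.40 (19 genes, camera adjusted p = 4e-07, but adjusted p = 0.891 with an estimated correlation), and immediate early and dissociation stress genes 0.56 (20 genes, 8.54e-05, but adjusted p = 0.891 with an estimated correlation). G2/M phase genes had a median of -0.23 (24 genes, 0.000241, but adjusted p = 0.275 with an estimated correlation). Camera also passed oxidative phosphorylation (median -0.42), ribosomal proteins (-0.46), mitochondrially encoded (1.69), S phase (-0.29) and APP family genes (0.11), and none of these held (smallest adjusted p = 0.891 with an estimated correlation). Genes called within the lists numbered 0, also when adjusted over the list alone. Without knockout-labelled replicate 1, which leaves 1 library in that group, 14 genes were lower and 0 higher, and without the filter on low counts 25 were higher and 25 lower. On simulated changes in genes with a mean of 20 or more counts, this comparison recovered 0 of 100 2-fold and 2 of 100 4-fold genes. Most changes of that size would thus be missed here.

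Against IgG, edgeR called 0 of 17062 genes higher or lower in the wildtype CPEB4 precipitates, with 1319 at an unadjusted p under 0.05, and DESeq2 called 5 higher and 9 lower. Ribosomal proteins had a median log2 fold change of -1.18 (32 genes, camera adjusted p = 8.56e-12, but adjusted p = 0.807 with an estimated correlation) and oxidative phosphorylation genes -1.01 (24 genes, 4.58e-08, but adjusted p = 0.807 with an estimated correlation). Cholesterol synthesis (-0.77), autism risk (0.44), S phase (-0.54), glycolysis (-0.61) and G2/M phase genes (-0.35) passed and were lost too (smallest adjusted p = 0.746 with an estimated correlation), and 2 cholesterol synthesis genes were lower when adjusted over the list alone. The 0 rested on the precipitates labelled knockout, which enter the common fit. A fit on the 4 wildtype libraries called 235 higher and 537 lower, and leaving out knockout-labelled replicate 1 or replicate 2 gave 113 and 431 or 101 and 410. In the fit of 4 libraries, 17 of 32 ribosomal protein genes and 7 of 24 oxidative phosphorylation genes were lower. Over its 235 higher and 537 lower genes, knockout-labelled replicate 1 had medians of 1.64 and -2.13 against the same IgG libraries that chose the genes (wildtype precipitates 1.62 and 1.39, and -1.67 and -1.35), and replicate 2 had medians of 0.22 and -0.10, so the replicates labelled knockout disagree and leave open whether these calls depend on CPEB4.

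Knockout-labelled precipitates against IgG also gave 0 of 17062 genes by edgeR, with 371 at an unadjusted p under 0.05 and 0 called by DESeq2. Without knockout-labelled replicate 2, which leaves 1 library in that group and takes the spread from the other groups, 783 genes were higher and 1616 lower. Ribosomal proteins had a median log2 fold change of -0.71 (camera adjusted p = 2.2e-10) and oxidative phosphorylation genes -0.57 (6.85e-06), and autism risk (0.44), mitochondrially encoded (-1.43), glycolysis (-0.41), cholesterol synthesis (-0.44) and S phase genes (-0.28) passed as well. All 7 were lost (smallest adjusted p = 0.596 with an estimated correlation). The number of genes higher in the wildtype precipitates than in all 3 controls was 0, and 12 without the filter on low counts.

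Against input, 4647 of 17062 genes were higher and 4680 lower in the wildtype CPEB4 precipitates (edgeR). Rn7sk, the RNA that holds a transcription elongation factor inactive, rose by 14.58 (SE 1.05, edgeR adjusted p = 0.000146), from 0.0316 ± 0.0120 to 944 ± 328 CPM (n = 2). The other 9 largest increases were mitochondrial transcripts at 0 in the inputs, from mt-Co2 (at least 24142-fold higher against 3 counts over the inputs), mt-Atp6, mt-Co1, mt-Co3, mt-Atp8, mt-Rnr2, mt-Nd5 and mt-Nd3 to mt-Ts1 (at least 2706-fold). Their bounds and order rest mostly on wildtype precipitate 2, with 1493 and 38170 counts of mt-Co2 and 169 and 4277 of mt-Ts1 in precipitates 1 and 2. Since all 37 mitochondrial genes are at exactly 0 in both inputs, whether the inputs were processed like the precipitates is open, and these values cannot be read as enrichment. The same doubt holds for Rn7sk, which had 2 and 1 counts in the inputs. The largest decreases among genes with counts in the precipitates were Opn1mw (-6.74, SE 0.58), the carbonic anhydrase gene Car1 (-6.32, SE 0.65), Prdx6b (-5.67, SE 1.12) and Cited1 (-5.35, SE 0.77), with edgeR adjusted p from 0.000191 to 0.00291. The precipitates held 4 and 2 counts of Opn1mw, 2 and 2 of Car1, 1 and 0 of Prdx6b and 1 and 1 of Cited1. The size and order of these decreases are therefore uncertain. Aldoart2 and Prdx2-rs3, at 0 in both precipitates, were at least 33.5-fold and 9.28-fold lower, and like Prdx6b are near-copies of abundant genes, so their counts are uncertain. Plpp2, the immunoproteasome gene Psmb8, Tnnc2 and S100a4 were also at 0, at least 1.60-fold to 2.84-fold lower. IgG differed from input in the same way for Rn7sk (15.19) and Opn1mw (-6.02), and Car1 was at 0 in IgG. For Prdx6b (-2.92) and Cited1 (-2.11) IgG fell less. In IgG against input Plpp2, Psmb8, Tnnc2 and S100a4 were not called (edgeR adjusted p from 0.0913 to 0.41).

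Gene lists divided by direction against input. Of 52 autism risk genes 37 rose and 2 fell (39 and 3 adjusted over the list alone), among them the transcription factor gene Zbtb20 (4.45, SE 0.61) and the Mediator gene Med13l (3.11, SE 0.44), with camera adjusted p = 4.63e-08 (adjusted p = 0.606 with an estimated correlation). IgG against input gave 26 higher and 1 lower in the same list, with Zbtb20 at 3.59 and Med13l at 2.42, and knockout-labelled precipitates against input 38 and 3. All 13 mitochondrially encoded genes passed as higher (2.75e-08, adjusted p = 0.606 with an estimated correlation), with the same doubt about the inputs. Of 24 oxidative phosphorylation genes 21 fell, such as the respiratory chain genes Cox7b (-3.31, SE 0.41) and Ndufb5 (-2.94, SE 0.38), and of 32 ribosomal protein genes 25 fell and 1 rose (26 and 1 adjusted over the list alone), such as Rps15 (-3.80, SE 0.59). Both lists had camera adjusted p = 5.44e-07 (adjusted p = 0.606 and adjusted p = 0.674 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 19 cases, among them Pmvk (-2.72, SE 0.40) and Mvd (-2.77, SE 0.43), ER stress genes in 16 of 20, glycolysis genes in 11 of 16, S phase genes in 13 of 24 and interferon response genes in 7 of 15. Their camera adjusted p values were 0.000415, 0.00852, 0.00814, 0.0196 and 0.0464, and none held (smallest adjusted p = 0.606 with an estimated correlation). Among 30 CPEB and poly(A) tail regulation genes 12 rose and 1 fell (camera adjusted p = 0.164), and the risen included Tent2 (3.46, SE 0.49), Cpeb3 (2.98, SE 0.50) and Cpeb4 (3.32, SE 0.61). In IgG against input 9 of the 30 rose, with Tent2 at 3.00, Cpeb3 at 2.16 and Cpeb4 at 2.52. In the neurogenic progenitor list, where 5 of 14 fell, the fatty acid binding protein gene Fabp7 fell by 4.57 (SE 0.59), and in the quiescence and astrocyte list, where 7 of 15 fell and 3 rose (8 and 3 adjusted over the list alone), the lipoprotein gene Apoe fell by 4.49 (SE 0.76). Camera did not pass these 2 lists (camera adjusted p = 0.22 and 0.294). IgG against input also fell for Cox7b (-2.52), Ndufb5 (-2.20), Rps15 (-2.61), Pmvk (-1.73), Mvd (-1.19), Fabp7 (-3.59) and Apoe (-3.20).

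Other lists held genes of both directions against input and did not pass camera. In the APP family and processing list 3 of 17 genes rose and 5 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.829), and the risen were led by the adaptor genes Apbb2 (3.60, SE 0.50) and Apba1 (3.69, SE 0.62). Microglia/macrophage genes rose in 2 of 6 cases and fell in 1 (0.284), with the purine receptor gene P2ry12 at 4.42 (SE 0.52), and IgG against input gave 3.92 for it. Of the BMP response list 5 of 9 genes fell and 1 rose (0.461), among them Id3 (-2.88, SE 0.67) and Hey1 (-1.96, SE 0.50). G2/M phase genes fell in 8 of 24 cases and rose in 2 (0.488), with the survivin gene Birc5 at -2.33 (SE 0.36) and the kinase gene Aurka at -1.52 (SE 0.33). Cleavage and polyadenylation genes rose in 6 of 23 cases and fell in 3 (0.829), with the RNA-binding gene Elavl2 at 2.60 (SE 0.52) and the nuclear poly(A) binding gene Pabpn1 at -2.86 (SE 0.69). EGF and ERK response genes rose in 4 of 17 cases and fell in 4 (4 and 3 adjusted over the list alone, 0.676), including Etv1 (2.47, SE 0.47) and Spred2 (2.16, SE 0.43). Immediate early and dissociation stress genes fell in 3 of 20 cases (2 adjusted over the list alone, 0.324), including the chaperone gene Dnajb1 (-2.34, SE 0.57) and Ier2 (-1.92, SE 0.48). Endothelial genes rose in 2 and fell in 2 of 4 cases (0.883), neuroblast genes rose in 1 and fell in 1 of 7 (0.579), and oligodendrocyte genes fell in 2 of 3 (0.22). Among lists that camera passed, the 2 genes of smallest p were Fen1 (-2.88, SE 0.47) and Dut (-2.44, SE 0.45) in S phase, H2-K1 (-3.23, SE 0.61) and Ifi27 (-3.54, SE 0.69) in interferon response, Tpi1 (-2.94, SE 0.53) and Ldha (-2.98, SE 0.59) in glycolysis, and Sdf2l1 (-4.15, SE 0.76) and Ern1 (2.87, SE 0.54) in ER stress. In IgG against input every gene named in this paragraph moved in the same direction, though some, such as Id3, did not pass. Values there were 2.68 for Apbb2, 2.22 for Apba1, -1.60 for Id3, -1.67 for Birc5, 1.92 for Elavl2, 1.99 for Etv1, -2.23 for Sdf2l1 and 2.40 for Ern1.

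IgG also differed from the inputs. IgG against input gave 3053 higher and 2607 lower genes, and knockout-labelled precipitates against input 4603 and 4260, all with the same 2 inputs. The IgG counts were 945 higher and 178 lower without IgG replicate 2, 1662 and 591 without IgG replicate 1, 1057 and 547 without input 1, 996 and 675 without input 2, and 420 and 11103 with scaling by total counts. Protein-coding genes higher in the wildtype CPEB4 precipitates than in input (3371) had a median length of 101.9 kb, those lower (3354) 9.37 kb and the rest 27.3 kb. IgG gave 118 kb and 8.74 kb, and knockout-labelled precipitates 101.4 kb and 9.14 kb. Small nuclear RNA genes rose in 37 of 38 cases in the wildtype precipitates and in 38 of 38 in IgG, and ribosomal RNA genes in 10 of 10 in both. Their median log2 fold changes in the wildtype precipitates were 12.9 and 9.71, and the doubt about how the inputs were processed holds for them too. Counts against input moved with single libraries and with scaling: without wildtype precipitate 1 they were 2916 higher and 2062 lower, without wildtype precipitate 2 they were 3637 and 2804, and without input 2 they were 2951 and 3357. Scaling by total counts shifted the median log2 fold change to -1.57 and gave 1057 higher and 7863 lower, so 11.9% of calls were higher against 49.8% with TMM.

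**Figure D5:**
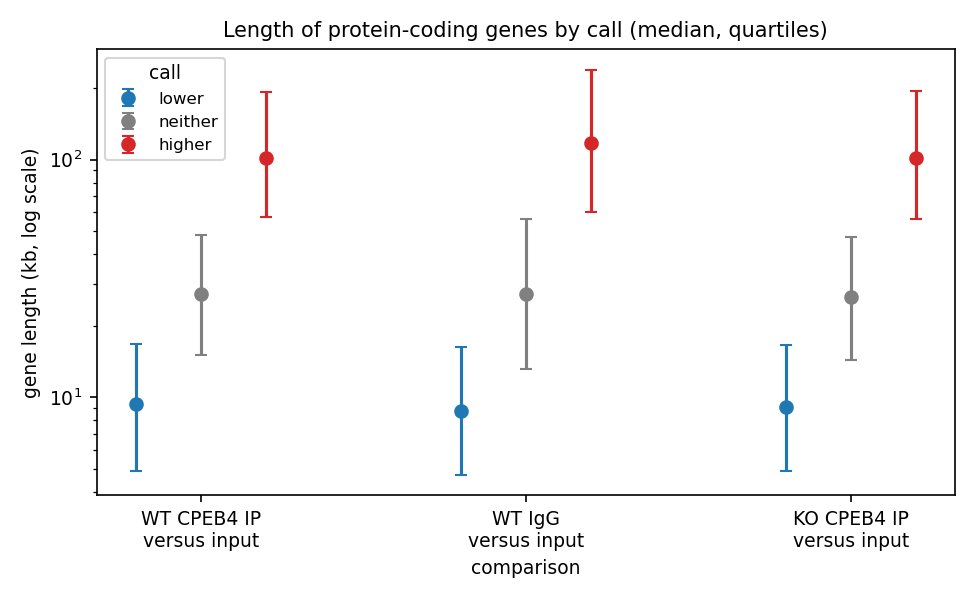
Length of protein-coding genes, in kb on a log scale, by call in 3 comparisons with the same inputs; points are medians and bars quartiles. Genes higher in the wildtype CPEB4 precipitates have a median of 101.9 kb and genes lower 9.37 kb, against 118 kb and 8.74 kb for IgG.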

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

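The tests weighed here were all chosen after the results were seen. In the hash tag table of the wildtype library, 1 barcode that is not a cell holds 518190 counts of tag 1, a signal in counts that no comparison uses. Tag 1 of that library has 808570 counts, 98.4% of them outside the cells, and the highest barcode outside the cells for tag 1 of the library labelled knockout holds 1349. Barcodes whose opening bases match a stretch of the leading barcode, in place or shifted by up to 2 bases, hold 669371 of the counts. They number 173 with the leading barcode itself, and their last bases were free to differ. The cause was not tested, and cells were assigned only from the counts of their own barcodes.

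Among tagged cells, Aplp1 transcripts of the library labelled knockout lie mostly on tag 2. Of the 54 counts of that library, 47 lie in cells without a mouse at the minimum of 10 tag counts. Free RNA, or reads from a part of the gene left in place, should spread over the tags. Of the counts in cells with 3 or more tag counts, 91.7% lie on tag 2 (22 of 24, permutation p = 2e-05, one-sided on the highest of the 3 tags). With 10 or more tag counts it is 7 of 7 (permutation p = 0.00177). In tagged cells this excludes either as the sole source, and cells without a tag are not covered. A mouse in the knockout pool that carries Aplp1 transcripts fits, since tag 2 stands at 94.2 CPM with 10 or more tag counts, where the lowest wildtype tag stands at 101 CPM on 4 counts, and at 123.7 against 230.2 CPM with 3 or more. Within quiescent NSC/astrocyte-like cells with 3 or more tag counts, tag 2 holds 19 counts (261 CPM, 157 to 407) and tags 1 and 3 hold 0. With 10 or more, tag 2 holds 6 counts (166 CPM, 61.0 to 362) and tags 1 and 3 hold 0. Makeup by cell class alone thus does not account for the difference between tags. The minimum of 3 is a weak assignment, as 27.3% of knockout-labelled cells of the other tags carry 3 or more counts of tag 2. An exchange of mice between the pools would leave a wildtype tag near the level of free RNA. That level was set at 53.8 CPM, the Aplp1 level of active NSC/transit amplifying-like cells of the wildtype library. Such cells hold a median of 708 RNA counts, against 314 in quiescent NSC/astrocyte-like cells, so free RNA could weigh more in shallower cells. With 10 or more tag counts, wildtype tags 2 and 3 lie above 53.8 CPM (229 CPM, 128 to 377, and 218 CPM, 137 to 331). This argues against an exchange of these mice only as far as that level holds for shallower cells. For tag 1, with 4 counts, it cannot be told (p = 0.167, one-sided exact Poisson). A minimum of 3 cannot settle it, because 22.3% of wildtype cells of the other tags carry 3 or more counts of tag 1.

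The share of cells assigned to a mouse runs from 98.6% in microglia/macrophage-like cells and 97.4% in endothelial-like cells through 28.0% in quiescent NSC/astrocyte-like cells to 2.91% in neuroblast-like cells. Levels of the antibody target fit, since MHC class I genes in the lowest of the well-tagged classes stand 13.5 times above those in the highest of the poorly tagged classes. Depth of the cells is excluded, because the active NSC/transit amplifying-like cells, of which 8.66% are assigned, hold 1.97 times the median RNA counts of microglia/macrophage-like cells. Ptprc, which encodes CD45, is not among the genes counted, so that target was not tested.

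The precipitates labelled knockout split: replicate 1 correlates with the wildtype CPEB4 precipitates at 0.971 and 0.951 and with IgG at 0.86 and 0.915, and replicate 2 with IgG at 0.956 and 0.95, with the wildtype CPEB4 precipitates at 0.923 and 0.93 and with replicate 1 at 0.871. Different amounts of background fit, since replicate 2 holds 75.2% of its counts in the 17 background loci, against 35.9% in replicate 1. These loci were chosen from the IgG libraries (75.4% and 70.8%), so an IgG library under this label would give a like share. The share therefore cannot tell background from a swap. A swap with a wildtype or IgG library cannot be told from these counts, because the lower correlation within those groups exceeds the highest between them by only 0.007 (0.968 within the wildtype precipitates, 0.945 within IgG, 0.938 between). Cpeb4 counts cannot settle it either, with 4825 and 1285 in these libraries.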

How the results depend on the processing

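Tests on the splits of mice, the crossed IgG numbers, removal of background loci, the 20-count tag minimum and the genes of shared reads were chosen after results were seen. Of 315 changed settings for the counts, shares and list medians in the report, 255 left the result on its side and within 1.5 times, and 60 were counted as moved. The 60 include culture list medians that stayed within 1.5 times, such as 5.7467 for BMP response with filtered cells against 5.7457. Among named genes 1249 stayed the same, 56 moved, 50 became weaker and 1 reversed. The reversal is Cpeb4 in the wildtype CPEB4 precipitates against IgG, whose log2 fold change was -0.13 without wildtype precipitate 1, a fit with fewer samples.

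Between wildtype and knockout-labelled precipitates, no filter gave 25 higher and 25 lower, and leaving out libraries gave 0 to 14 lower. Against IgG, DESeq2 gave 5 and 9, no filter 50 and 115, the 4 libraries alone 235 and 537, and leaving out libraries 0 to 113 higher and 0 to 431 lower. Against input, total counts gave 1057 and 7863, and leaving out libraries 2916 to 5754 higher and 2062 to 5886 lower. Knockout-labelled precipitates against IgG gave 15 and 1 with no filter, and 0 to 783 higher and 0 to 1616 lower without single libraries, where a group left with 1 library takes its spread from the others. Genes above all 3 controls numbered 12 with no filter. Camera with an estimated correlation passed 0 lists in each of the 4 contrasts, where the preset passed 8, 7, 9 and 7. Removing the background loci or using DESeq2 size factors changed none of these counts by over 1.5 times. Apart from fits with fewer samples, the cause was not tested.

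The replicate number as a block gave 0 calls in the 3 contrasts between precipitates and 4597 higher and 4532 lower against input. Correlations of replicate deviations were 0.103 to 0.335 among input, wildtype and knockout-labelled precipitates, -0.367 to -0.177 between these and IgG, and -0.114 to 0.0412 for the tags. As not every pair of groups correlates and the labels name no shared culture, the samples are taken to share only a number, although crossed IgG numbers stay open. With the IgG numbers crossed, the block gave 0 higher and 1 lower against IgG and 5232 higher and 5230 lower against input. In the mouse sums the block gave 0 calls over all cells and 2 higher in the quiescent NSC/astrocyte-like class.

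For the mice, the 1 gene called over all cells became 0 with DESeq2, a tag share of 90%, HTODemux, the block and 20 or more tag counts, and 0 to 1 without single mice. The quiescent NSC/astrocyte-like class gave 0 to 1 higher and 0 to 1 lower without single mice. The 10 splits of the 6 mice are too few for a share under 0.05: over all cells the real value is 1 and the highest other 0, met by 1 of 10, and within the quiescent NSC/astrocyte-like class 0 and 0, met by 10 of 10. Active NSC/transit amplifying-like cells differed by 6.70 points with genes of shared reads kept (exact permutation p = 0.1, unadjusted, the smallest this design allows). Microglia/macrophage-like cells differed by 5.55 points at a tag share of 90% and 7.00 points with 20 or more tag counts (exact permutation p = 0.3 for each). The cause was not tested. Mouse sums hold 39583 to 100734 counts, at which 44 of 100 simulated 2-fold and 93 of 100 simulated 4-fold changes were recovered. These rates hold only for genes with a mean of 20 or more counts per mouse, and recovery at fewer counts was not simulated. Effects of depth on the calls were not tested.

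In the cultures, list medians under TMM, per-cell means and filtered cells were 5.61, 5.69 and 5.75 for BMP response, 0.0790, 0.184 and 0.22 for EGF and ERK response, -3.41, -3.31 and -3.26 for G2/M phase, and 1.96, 2.06 and 2.10 for quiescence and astrocyte. Shares of cells with Mki67, Top2a or Cdk1 were 19.1% and 78.9% unthinned, as deeper cells show more genes. Of thinned BMP4 and EGF cells, 6.54% and 74.1% had 2 or more G2/M transcripts and 24.9% and 87.0% had 1 or more, with free RNA not measured. The motif test of cytoplasmic polyadenylation elements and its alternatives (the shorter motif alone, the shortest 3′UTR) were not run.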

Other observations

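In the fresh wildtype library Aplp1 had 176 counts in quiescent NSC/astrocyte-like cells (385 CPM), 26 in neuroblast-like cells (175.7 CPM), 20 in active NSC/transit amplifying-like cells (53.8 CPM), 9 in mature neuron-like cells (484 CPM) and 0 in microglia/macrophage-like and endothelial-like cells. In the library labelled knockout it had 37 (122 CPM), 8 (50.4 CPM), 1, 1, 0 and 0 counts in these classes.

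In a test chosen after the result was seen, across protein-coding genes the log2 fold change against input rose with gene length, with Spearman correlations of 0.742 for the wildtype CPEB4 precipitates, 0.681 for IgG and 0.728 for the precipitates labelled knockout, all with the same 2 inputs. Of 1526 pseudogenes 797 fell and 191 rose in the wildtype precipitates, and of 903 long noncoding RNAs 383 rose and 130 fell. In IgG against input 437 pseudogenes fell and 220 rose, and 275 long noncoding RNAs rose and 73 fell. Mitochondrial genes had 0 counts in both inputs, and the cause was not tested. Fosb, an immediate early gene, had 411 counts in the first input and 12 in the second.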
